A study of Mus musculus with 48 samples.

How the data were processed

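Striatal RNA of 16 mice aged 50 days was sequenced, 8 mice of a congenic line and 8 wild-type C57BL/6J littermates, with 4 females and 4 males in each genotype. The labels name the congenic segment by its size of 112 kb. As background knowledge of this line, the segment comes from the DBA/2J strain, lies on chromosome 11 and holds Hnrnph1 and Rufy1. Tissue punches of 3 mm from both sides of each brain were pooled per mouse, per the labels. The library of each mouse was run on 3 lanes, which gives 48 runs. Mice are named as in the headings of the deposited columns, Sample_ and the number of the mouse.

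The authors deposited a table of read counts per gene and a table of read counts per exon bin, both as whole numbers that had not been normalised. An exon bin is a stretch of exon with the same set of overlapping transcripts. The submitters' processing notes name FastQC 0.10.1, HTSeq 0.6.1p1, edgeR 3.8.6 and limma 3.22.7, with no role for each. The aligner is not given in the sources used here. The labels disagree on the reads: the design text gives 50 bp single-end reads, and the extraction protocol gives 100 bp paired-end reads from a stranded mRNA kit. They also list 2 genome builds, mm9 and mm10. Of the cells of the gene table that hold 1 to 10 counts, 62.0% were even. Cells of 2 counts numbered 31877 and cells of 1 count 15048, an excess that separate counting of the mates of a pair would give. The layout of the reads is not settled by this, so a count is called a count here. Exon bins rebuilt from the GENCODE annotation of NCBIM37 (mm9) had the same number as the deposited bins for 16977 of 17389 genes with at least 5 bins (97.6%), so coordinates are given on that build. The setting for strand in the counting is not given in the sources used here, so overlapping antisense genes may share counts.

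The 3 runs of a mouse were compared by chi-square over genes with at least 30 counts in that mouse. Their dispersion index, chi-square over degrees of freedom, was 1.89 to 1.94 with a median of 1.92. That is above the index that independent counts of a single library would give, and the reason was not tested. Single runs of different mice of the same genotype and sex gave 4.97 to 30.7 with a median of 11.4 over 24 pairs. The runs of a mouse were therefore summed and n counts mice. The summed totals were 73.1 to 82.0 M counts per mouse (M for the mega prefix) in 23420 genes, and 118.5 to 133.2 M in 368092 exon bins. Of the gene groups in the exon table, 908 join overlapping genes, and a bin of such a group cannot be given to a single gene.

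All computations used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0, and Python 3.11.15. Genes were kept by the edgeR filter on the genotype-by-sex groups, with a minimum count of 10 and a minimum total of 15. Counts were scaled by TMM. The main test was the edgeR quasi-likelihood test with robust dispersions, with sex in the model for genotype and genotype in the model for sex. The genotype effect within each sex and the interaction came from a model with both terms and their product over all 16 mice. Exon usage was tested with edgeR's diffSpliceDGE, which sets each bin against the rest of its gene, and genes were called by the Simes method. A call needed a Benjamini-Hochberg adjusted p under 0.05. All tests were two-sided, except where a one-sided test is named. Intervals are at 95%. Those of exon bins were built from the SE with a normal distribution, and for some genes these SEs are smaller than the p values of the test imply. Values per mouse are counts-per-million (CPM) or the share of a gene's exon counts in a bin.

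The main tests, the gene lists, the rule for named genes and the alternatives not named below as later were fixed before the data were examined. The lists were 25 in all: the congenic interval, its neighbours, hnRNPs, other splicing factors, pan-MSN, D1-MSN, D2-MSN, interneuron, dopamine signalling, immediate early, astrocyte, oligodendrocyte, OPC, microglia, endothelial and mural, blood, cortical excitatory neuron, thalamus, septum and pallidum, choroid plexus, ependyma, heat shock, oxidative phosphorylation, cytosolic ribosomal proteins and sex chromosome. MSN stands for the medium spiny neurons of the striatum, and OPC for oligodendrocyte precursor cells. Of 495 listed names, 493 were in the gene table, 9 of them under an older symbol. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the 25 lists. A list score per mouse, the centred mean log2 CPM of its genes, was tested by an exact permutation over 12870 splits of the mice into 8 and 8.

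The rule for named genes took Hnrnph1, Rufy1 and the 20 genes of smallest p for genotype, the 20 genes of smallest Simes p for exon usage, the 20 of smallest p for sex (applied to expression and to exon usage), and the 10 of smallest p for the interaction and within each sex. Genes named under a list were taken in order of p. Genes outside this rule are said to be so where they are named.

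The gene steps were tested on simulated counts with 50 genes changed at each fold. For each comparison the changes at all folds were made together, and genes were drawn independently, with no correlation between genes. A gene changed alone would face a stricter adjusted threshold. The shares below therefore overstate how well a few small changes would be found. For genotype, 78% of genes changed 1.25-fold and 94% of genes changed 2-fold were recovered, with 6 false calls over 16590 genes. For sex the shares were 60% and 92%, and for the interaction 8% and 84%. Within females they were 32% and 92%, and within males 34% and 84%. For exon usage by genotype, 12% of genes with a bin changed 1.25-fold, 70% at 1.5-fold and 94% at 2-fold were recovered, and for exon usage by sex 24%, 70% and 80%. Simulated exon bins had only the spread of the trend over all bins, and changes were placed only in genes with several bins. Real bins can be more uneven, so these shares may be overstated for that reason too.

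Alternatives were other tests, scalings, filters and covariates, single lanes, the 48 runs in place of summed mice, single sexes or genotypes, and leaving out each mouse in turn. Those chosen after the data were seen were the score of the cortical excitatory neuron list as a covariate in every comparison it was used in, upper-quartile scaling for sex, bins with a count in every mouse, all alternatives for exon usage by sex, the list tests without each mouse, the sex fits without mice Sample_4804 and Sample_4806 together, picked after they stood apart in counts of Smyd3 and also the highest in Rn45s, the list tests by sex without Sample_4753 as well, picked as the lowest 3 in pan-MSN score, and pairs of neighbouring mouse numbers of 1 sex as a block, in place of sex, for genotype. Other splits of the mice were also fitted, 100 for gene expression, 35 within a sex and 21 for exon usage, the real one included.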

Results

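RNA from the striatum, a forebrain region made up mostly of medium spiny neurons, was sequenced in 8 mice of a congenic line and 8 wild-type littermates, with 4 females and 4 males in each genotype. The congenic mice held 77.0 ± 2.92 M gene counts (SD, n = 8) and the wild-type mice 78.1 ± 3.09 M (SD, n = 8). Exon bins held 126 ± 4.21 M counts in congenic and 127 ± 4.97 M in wild-type mice (SD, n = 8 each). The title of the series names differential splicing as its question.

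Hnrnph1 and Rufy1, the genes of the congenic interval, had the same transcript level in both genotypes within the spread between mice. Hnrnph1 encodes an RNA-binding protein of the hnRNP H family that takes part in splicing, and lies at chromosome 11, 50190492 to 50200030, on NCBIM37. Its level was 361 ± 20.6 CPM in congenic and 359 ± 18.1 CPM in wild-type mice (SD, n = 8 each), a log2 fold change of 0.01 with a 95% interval of -0.07 to 0.09. Rufy1, which encodes an endosomal protein and lies at 50202788 to 50244627, was at 38.4 ± 2.12 and 38.5 ± 1.34 CPM (SD, n = 8 each), with a 95% interval of -0.08 to 0.08 on the log2 scale. The adjusted p was 0.999 for both in edgeR's quasi-likelihood test.

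**Figure D1:**
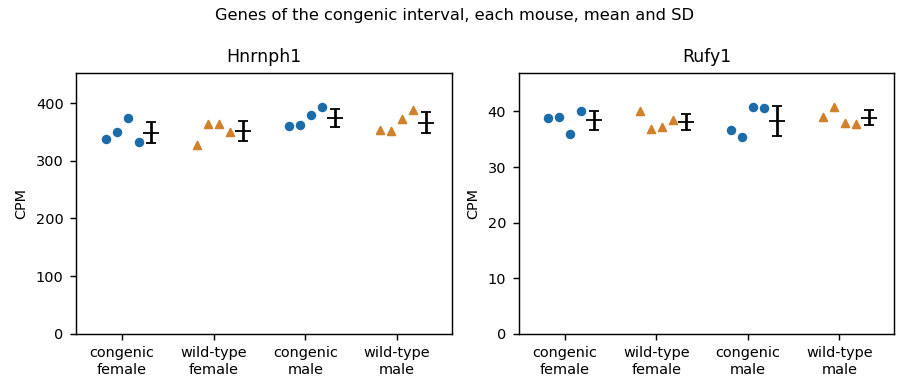
CPM of Hnrnph1 and Rufy1 in each of the 16 mice by genotype and sex, with the mean and SD of each group of 4 beside the points. The congenic and wild-type points overlap for both genes, at 361 and 359 CPM on average for Hnrnph1.

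Among all 16716 genes tested, edgeR called 0 genes between the genotypes, with 256 at an unadjusted p under 0.05 where uniform p values would give 836. DESeq2 called 0 with 268 at that level, and limma-voom 0 with 277. The 20 genes of smallest p did not pass, each with an adjusted p of 0.999 in edgeR. Trib3, a pseudokinase induced by cell stress, was at 2.37 ± 0.317 CPM in congenic and 3.17 ± 0.661 CPM in wild-type mice (SD, n = 8 each), a log2 fold change of -0.42 (SE 0.12). Cav1, the main coat protein of caveolae, was at 14.6 ± 0.528 and 13.2 ± 0.929 CPM (SD, n = 8 each), with 0.15 (SE 0.05). C3ar1, the receptor of complement fragment C3a, had 0.22 (SE 0.08), Hcn3, a pacemaker channel, -0.21 (SE 0.07), Tle3, a transcriptional corepressor, -0.17 (SE 0.05), and Col26a1, a collagen, 0.30 (SE 0.08). The largest values among the 20 belonged to genes of low level, such as Cdsn at 0.110 ± 0.0580 and 0.242 ± 0.104 CPM (SD, n = 8 each): Cdsn with -1.14 (SE 0.32), Gm14207 with -0.92 (SE 0.25), Cct6b with -0.91 (SE 0.31) and F2rl1 with -0.82 (SE 0.24). The others were Iqch, Asb16, Gm12522, Apol10b, Bbs10, Immp2l, Gm1564, Sh3bgr, Tmem200c and Mrps16, with log2 fold changes of -0.72 for Asb16 to 0.58 for Gm1564. For 85.8% of genes the 95% interval of the log2 fold change lay within 0.5 of 0.

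The gene groups fixed beforehand moved little with genotype, and 0 of their members passed over all genes or when adjusted over the list alone. In the camera test with a preset correlation, cytosolic ribosomal protein genes were higher in congenic mice, with 59 of 60 tested members positive and a median log2 fold change of 0.09 (adjusted p = 6.55e-19; adjusted p = 0.575 with an estimated correlation). Rps10 had 0.13 (SE 0.06) and Rps29 0.17 (SE 0.08). Congenic mouse Sample_4673 had a ribosomal score of 0.43 where the other congenic mice had -0.13 to 0.13, and without it the median was 0.03 with 56 of 60 positive (camera adjusted p = 1.86e-05). Oxidative phosphorylation genes were higher, with 37 of 42 positive and a median of 0.05 (adjusted p = 1.36e-08; adjusted p = 0.575 with an estimated correlation), among them Sdhc with 0.08 (SE 0.04), and the median was 0.03 without mouse Sample_4673. Markers of cortical excitatory neurons, which a striatal punch can include, were lower, with 2 of 20 positive and a median of -0.17 (adjusted p = 2.65e-05; adjusted p = 0.575 with an estimated correlation). Bhlhe22 had -0.35 (SE 0.18) and Slc17a7, the vesicular glutamate transporter of cortical neurons, -0.54 (SE 0.42), and the list's median was -0.08 without mouse Sample_4734, -0.11 without Sample_4739 and -0.31 without Sample_4804. Interneuron genes were lower (adjusted p = 0.0072; adjusted p = 0.575 with an estimated correlation), a call lost without mouse Sample_4673 (adjusted p = 0.218). The call of sex chromosome genes as higher, with a median of 0.09 (adjusted p = 0.00989; adjusted p = 0.575 with an estimated correlation) was lost without wild-type mouse Sample_4806, with a median of 0.04 (adjusted p = 0.532). That mouse had a score of -2.76 where the other females had -1.40 to -0.18, and the call was also lost without mouse Sample_4737 (adjusted p = 0.180). The call of microglia genes as higher (adjusted p = 0.0499; adjusted p = 0.842 with an estimated correlation) was lost in 10 of the 16 fits that each left out 1 mouse. It was also lost with pairs of neighbouring mouse numbers as a block, and the direction of the list turned with the cortical score as a covariate. Camera with an estimated correlation called 0 lists. The fry test called 0 lists, with adjusted p = 0.936 for all 25, and with either test 0 lists were at an unadjusted p under 0.05.

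The other lists were not called by genotype, and camera gave these adjusted p values. They were 0.942 for the congenic interval, 0.854 for the interval neighbours, 0.430 for hnRNPs and 0.239 for other splicing factors. Among striatal neurons they were 0.854 for pan-MSN, 0.729 for D1-MSN, 0.914 for D2-MSN and 0.854 for dopamine signalling. Immediate early genes had 0.430 and heat shock genes 0.0948. Among other cell types they were 0.917 for astrocyte, 0.0568 for oligodendrocyte, 0.251 for OPC, 0.119 for endothelial and mural and 0.239 for blood. Only 2 of the 8 listed blood genes were tested, so that list says little about blood content. Among neighbouring tissues they were 0.200 for thalamus, 0.729 for septum and pallidum, 0.707 for choroid plexus and 0.0568 for ependyma. For D1-MSN, astrocyte and septum and pallidum the median or mean and the camera direction differed in sign.

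The use of exons in Hnrnph1 and Rufy1 did not differ detectably between the genotypes in the bins tested. Of 48 Hnrnph1 bins, 46 were tested, with log2 fold changes against the rest of the gene of -0.11 to 0.08. Bin 1, the first UTR bin, was not tested, with means of 7 counts in congenic and 6.5 in wild-type mice. Bins 2 to 5, also in the UTR, held few counts, with means of 18.8 to 63.9 in congenic mice. The 95% interval of bin 2 was -0.41 to 0.19, so use of these leading bins was less well bounded. Of 24 Rufy1 bins, 23 were tested, with -0.08 to 0.11. The smallest p was 0.291 for bin 37 of Hnrnph1 and 0.157 for bin 8 of Rufy1 in edgeR's diffSpliceDGE, so 0 bins were at an unadjusted p under 0.05. Adjusted over these 2 genes, the smallest adjusted p in edgeR was 0.973. All tested bins of both genes had 95% intervals within 0.5 of 0. These intervals are approximate. For Rufy1 they are narrower than the p values of the test imply, as at bin 8 with -0.16 to 0.007 and p = 0.157 in diffSpliceDGE. The limma diffSplice test also called 0 bins and had 1 at an unadjusted p under 0.05.

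**Figure D2:**
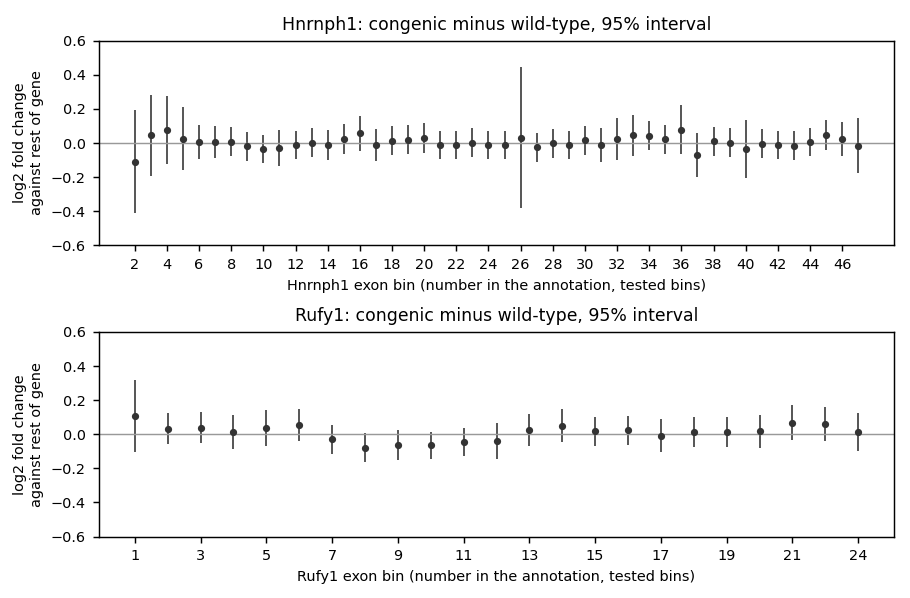
Log2 fold change of each tested exon bin against the rest of its gene, congenic minus wild-type, for Hnrnph1 and Rufy1, with vertical lines for the approximate 95% interval. The points lie between -0.11 and 0.11 and the intervals of all tested bins include 0.

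Across 14875 genes with 235478 bins, 1 gene was called for exon usage by genotype. It was Magi2, which encodes a synaptic scaffold protein, in a group of overlapping Magi2 models, at bin 34, a stretch of 677 bp holding coding sequence and UTR at chromosome 5, 20211191 to 20211867. The bin took a larger share in congenic mice, 0.0919 ± 0.0648% of the gene's exon counts against 0.0193 ± 0.0231% (SD, n = 8 each), a log2 fold change of 1.48 (SE 0.25; Simes adjusted p = 0.00412 in edgeR). The bin held 0 to 22 counts per mouse, with a count in 7 of 8 congenic and 5 of 8 wild-type mice. An exact permutation of its share, without regard to sex, gave p = 0.00995. That p is not adjusted for the choice of this bin on the same mice, so it adds no support to the call. The call was lost with limma diffSplice (bin adjusted p = 0.687) and with the cortical score as a covariate (log2 fold change 1.19), while a stricter filter, bins counted in every mouse and each lane or sex alone removed the bin before the test. It was also lost without mouse Sample_4673, Sample_4712, Sample_4734, Sample_4738, Sample_4739 or Sample_4806, with 0 genes called each time.

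At an unadjusted Simes p under 0.05 there were 73 genes where uniform p values would give 744, and 2461 bins where they would give 11774. The gene-level F test called 2 genes, Eif2s3y and Kdm5d, which lie on the Y chromosome and hold few counts in females, and these were named after their values were seen. The next 19 genes by Simes p did not pass, each with an adjusted p of 1 in edgeR. Dnase2a, a lysosomal nuclease, had -0.72 (SE 0.18) at bin 20, in the UTR, with shares of 1.18 ± 0.474% and 2.46 ± 0.751% (SD, n = 8 each). Zfp879 had 0.69 (SE 0.19) at bin 2, Itga4, an integrin subunit, -0.97 (SE 0.26) at bin 17, and Lama4, a laminin chain, -0.79 (SE 0.21) at bin 8. Cenpo, a centromere protein, had 0.74 (SE 0.18) at bin 2. The others were Eif2s3y, Commd10, Thop1, Pigz, Ccdc21, A430107O13Rik, Dnajc11, Mid1, Tmem164, Gprasp2, Gm12258, Nhsl1, Phf12 and Rbpjl.

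Males and females differed in 23 genes, 13 higher and 10 lower in males, out of 16716, with 12 on X or Y and 11 elsewhere. The males were numbered Sample_4671 to Sample_4734, and every female except Sample_4676 and Sample_4677 was numbered above all males. Outside X and Y, sex therefore cannot be cleanly told apart from what mouse numbers stand for. This limit holds for genes, gene lists and exon usage by sex. The largest differences among the 23 were in genes of the Y chromosome and in Xist, the RNA that coats the inactive X, which had a log2 fold change of -8.17 (SE 1.05). Among the Y genes were Uty with a log2 fold change of 9.05 (SE 0.25), Kdm5d 8.20 (SE 0.31), Ddx3y 8.20 (SE 0.31), Eif2s3y 7.79 (SE 0.30) and Uba1y 6.72 (SE 0.34), against traces in females. The sizes depend on traces in females: 7 females held 13 to 213 counts of Ddx3y, Eif2s3y, Kdm5d and Uty together, mouse Sample_4806 held 7, and males held 13555 to 15622. X-linked genes that escape silencing in females were lower in males: Eif2s3x at 118 ± 4.44 CPM against 176 ± 24.1 CPM (SD, n = 8 each), a log2 fold change of -0.58 (SE 0.07), Kdm6a with -0.54 (SE 0.06), Ddx3x with -0.40 (SE 0.04) and 5530601H04Rik with -0.38 (SE 0.06). Xist was at 1103 ± 494 CPM in females and 4.10 ± 5.50 CPM in males (SD, n = 8 each), and Jpx, its activator, had -0.48 (SE 0.08). The wild-type mouse Sample_4806, recorded as female, had 2.64 CPM of Xist where the other 7 females had 951 to 1549 CPM.

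**Figure D3:**
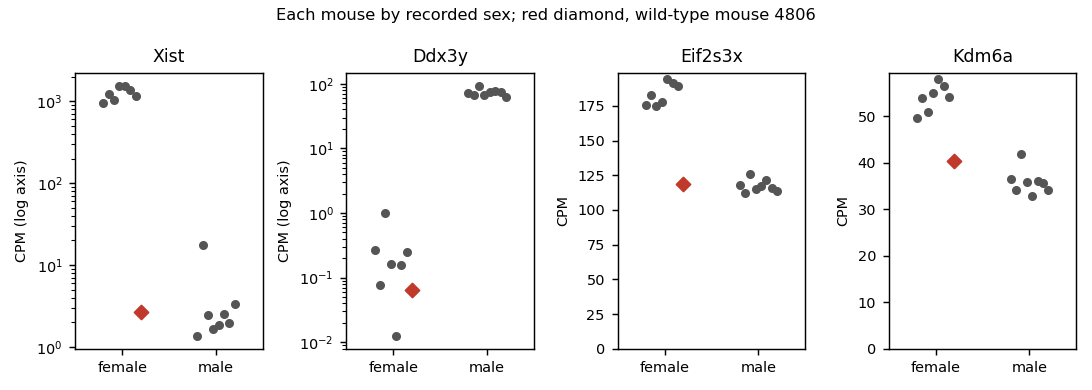
CPM of Xist and Ddx3y (log axes) and of Eif2s3x and Kdm6a (linear axes) in each mouse by recorded sex, with wild-type mouse Sample_4806 as a red diamond. Mouse Sample_4806 has 2.64 CPM of Xist, against 951 to 1549 CPM in the other 7 females, and lies among the males for Eif2s3x with 119 CPM.

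Genes with no counterpart on the Y chromosome also differed. Spry2 and Spry4, feedback inhibitors of growth factor signalling, were higher in males, with log2 fold changes of 0.38 (SE 0.07; adjusted p = 0.0151 in edgeR) and 0.58 (SE 0.11; adjusted p = 0.0457 in edgeR). Nab2, a corepressor of EGR transcription factors, had 0.29 (SE 0.05), Htr1b, a serotonin receptor, 0.56 (SE 0.10), Slc4a11 0.67 (SE 0.12), Zfp516 0.20 (SE 0.04) and the X-linked Egfl6 0.52 (SE 0.10). Col26a1 was lower in males, at 5.07 ± 0.613 CPM against 7.52 ± 1.46 CPM (SD, n = 8 each), and so was Tfrc, the transferrin receptor, with -0.31 (SE 0.06). Hspb1, a small heat shock protein, rose by 0.59 (SE 0.12; adjusted p = 0.0488 in edgeR), and Fmn1 and Opn4, outside the rule for named genes and named after their values were seen, were lower with -0.48 and -0.89. DESeq2 called 259 genes and limma-voom 19. The edgeR count ranged from 12, without mouse Sample_4672 or Sample_4731, to 76, without mouse Sample_4712, and was 15 without mouse Sample_4806. Outside X and Y the count of 11 became 1 without mouse Sample_4672 or Sample_4731, 2 without Sample_4753 or Sample_4804 and 4 without Sample_4806. It was 2 with both Sample_4804 and Sample_4806 left out, 2 with 1 surrogate variable and 62 without Sample_4712. Not all were among the original 11. Those held 2 of the 4 without Sample_4806, 1 of the 2 without both mice, 1 of the 2 with 1 surrogate variable and 11 of the 62 without Sample_4712.

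Immediate early genes, which neurons switch on within minutes of activity, were higher in males as a group, with the limit on mouse numbers given above. Of 22 tested, 0 passed over all genes and 15 were higher when adjusted over the list alone, with a median log2 fold change of 0.63 (camera adjusted p = 5.93e-13; adjusted p = 0.238 with an estimated correlation). Nr4a1 had 1.52 (SE 0.35), Per1 0.67 (SE 0.16), Egr3 0.37 (SE 0.09) and Sik1 0.36 (SE 0.10). Heat shock genes were higher, with 1 of 14 over all genes and 8 adjusted over the list alone, a median of 0.20 (camera adjusted p = 1.38e-08; adjusted p = 0.165 with an estimated correlation). Hspa1b had 0.99 (SE 0.23), Hspa8 0.23 (SE 0.06) and Dnajb1 0.22 (SE 0.06). By exact permutation of list scores the adjusted p was 0.0614 for immediate early genes and 0.0440 for heat shock genes.

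Markers of the striatal projection neurons were also higher in males in camera's test with a preset correlation. Of 25 pan-MSN genes, 0 passed over all genes and 7 were higher adjusted over the list alone, with a median of 0.10 (camera adjusted p = 3.23e-08; adjusted p = 0.381 with an estimated correlation). Ptpn5, a striatum-enriched phosphatase, had 0.21 (SE 0.05) and Meis2, a transcription factor, 0.13 (SE 0.04). Of 10 D1-MSN genes, 0 passed over all genes and 4 were higher adjusted over the list alone, with a median of 0.15 (camera adjusted p = 2.79e-05; adjusted p = 0.133 with an estimated correlation). Drd1a, the dopamine D1 receptor, had 0.13 (SE 0.04) and Isl1 0.15 (SE 0.04). The exact permutation of list scores gave an adjusted p of 0.0175 for D1-MSN. It gave 0.0614 for pan-MSN, 0.150 for D2-MSN and 0.287 for dopamine signalling, which did not pass. Of 9 D2-MSN genes 1 was higher adjusted over the list alone, Gpr52 with 0.20 (SE 0.06; camera adjusted p = 0.0104; adjusted p = 0.482 with an estimated correlation). Dopamine signalling genes had 0 of 32 by either count (camera adjusted p = 0.0130; adjusted p = 0.482 with an estimated correlation), and that call was lost without mouse Sample_4671 or Sample_4806. Females Sample_4753, Sample_4804 and Sample_4806 had the lowest pan-MSN scores, at -0.12, -0.20 and -0.14, where the other 5 females had -0.04 to 0.04. The same mice had cortical scores of 0.41, 0.55 and 0.43, septum and pallidum scores of 0.55, 0.41 and 0.16 and ependyma scores of 0.29, 0.86 and 0.63, although female Sample_4676 and male Sample_4734 also had cortical scores of 0.45 and 0.61. The highest septum and pallidum score, 0.64, also belonged to a mouse outside these 3. Leaving out the 3 mice lowest in the score lowers the difference by construction, and the pan-MSN median was then 0.03 (camera adjusted p = 0.0054) and the D1-MSN median 0.09 (camera adjusted p = 0.000655), and D2-MSN and dopamine signalling were no longer called (adjusted p = 0.344 for both).

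Markers of cortical excitatory neurons were lower in males, with 5 of 20 positive and a median of -0.20, and 0 passed by either count (camera adjusted p = 0.0468; adjusted p = 0.714 with an estimated correlation). Oligodendrocyte genes were lower, with 2 of 15 positive and a median of -0.11 (camera adjusted p = 0.0468; adjusted p = 0.714 with an estimated correlation), and ependyma genes were lower, with 0 of 12 positive (camera adjusted p = 0.0433; adjusted p = 0.714 with an estimated correlation). Of the 16 fits that each left out 1 mouse, 12 lost the cortical call, 8 the oligodendrocyte call and 9 the ependyma call. The score of the cortical list spanned -0.79 to 0.61 over the mice on the log2 scale. Ribosomal protein genes were higher, with 57 of 60 positive and a median of 0.10, and 2 passed adjusted over the list alone, Rpl28 with 0.19 (SE 0.05) and Rps28 with 0.23 (SE 0.06; camera adjusted p = 5.58e-09; adjusted p = 0.657 with an estimated correlation). Male Sample_4673 had a score of 0.43 where the other males had -0.13 to 0.13, and without it the median was 0.04 with 46 of 60 positive (camera adjusted p = 0.00587). Oxidative phosphorylation genes had a median of 0.05 (camera adjusted p = 0.00191; adjusted p = 0.657 with an estimated correlation), and the call was lost without mouse Sample_4673 (adjusted p = 0.0766). Microglia genes had a median of 0.09, with Trem2 and C1qc higher and Fcrls lower adjusted over the list alone (camera adjusted p = 0.00897; adjusted p = 0.657 with an estimated correlation), a call also lost without mouse Sample_4673 (adjusted p = 0.0674). The sex chromosome list, 4 higher and 4 lower of 10 over all genes, was the 1 list called with an estimated correlation (camera adjusted p = 3.22e-31; adjusted p = 0.00118 with an estimated correlation), and its median of -0.26 and mean of 2.29 differed in sign. The fry test called it with D1-MSN, heat shock and immediate early genes. Without mouse Sample_4806, 9 lists were called by camera in place of 13, and 8 with Sample_4804 left out as well.

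The other lists were not called by sex, and camera gave these adjusted p values. They were 0.422 for the congenic interval, 0.915 for its neighbours, 0.107 for hnRNPs, 0.422 for other splicing factors and 0.0569 for interneuron. They were 0.440 for astrocyte, 0.827 for OPC, 0.475 for endothelial and mural, 0.875 for blood, 0.827 for thalamus, 0.952 for septum and pallidum and 0.464 for choroid plexus. Here too only 2 of the 8 listed blood genes were tested. For the neighbours and for septum and pallidum, the median, mean and camera direction differed in sign.

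**Figure D4:**
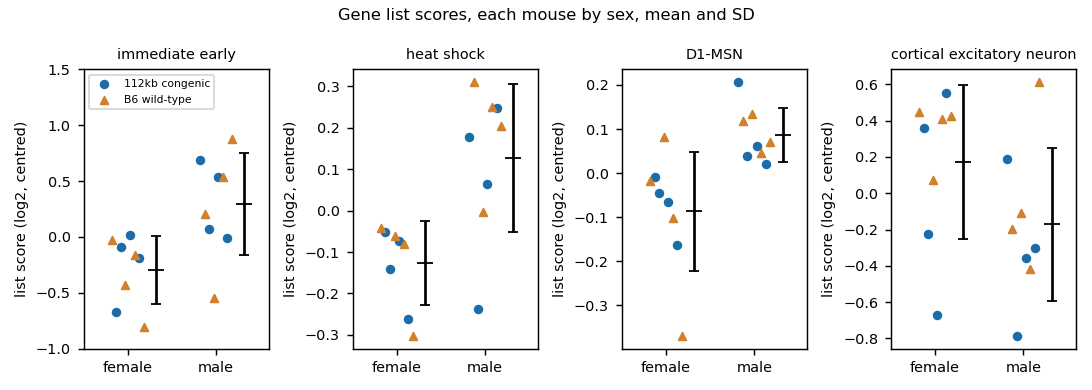
Score of 4 gene lists (mean log2 CPM of the list, centred) in each mouse by sex, circles for congenic and triangles for wild-type mice, with the mean and SD of each sex beside the points. The scores of the cortical excitatory neuron list span -0.79 to 0.61, and both sexes overlap in each list shown.

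Exon usage differed between the sexes in 19 genes by the Simes test, and in 2 of these genes with mice Sample_4804 and Sample_4806 both left out. Those females had the highest share of Rn45s, at 0.376% and 0.439%, and the highest share of all 16 mice in 6 of the 20 named bins. The other females had 0.205 to 0.327% Rn45s and the males 0.160 to 0.263%. Genes with at least 10 counts numbered 16331 to 16648 in females and 16292 to 16384 in males. Most females lay above every male in both measures, so the libraries also differed between the sexes. Tested bin by bin, 37 bins were called, 8 with a larger and 29 with a smaller share in males, of which 25 lay in those 19 genes and 12 elsewhere. Of the 37 bins, 21 lay in exons annotated as noncoding, 3 higher and 18 lower, a class that made up 7.8% of the bins tested. Smyd3, a methyltransferase, had -1.47 (SE 0.19) at bin 16 (Simes adjusted p = 2.05e-08 in edgeR), with shares of 0.198 ± 0.111% in males and 0.829 ± 0.989% in females (SD, n = 8 each). Those 2 females held 106 and 118 of its counts, the other 6 females 9 to 16 and the males 2 to 15. Ppp3ca, a calcineurin subunit, had -0.40 (SE 0.06) at bin 30, and an exact permutation of its share gave p = 0.0690. Srsf10, a splicing factor, had -0.33 (SE 0.06) at bin 9, with shares of 2.01 ± 0.342% in males and 2.79 ± 0.375% in females (SD, n = 8 each). Rbm3, an X-linked RNA-binding protein induced by cold, had 0.43 (SE 0.08) at bin 2, and Pkd2, a calcium-permeable channel, had 0.849 ± 0.193% against 1.31 ± 0.0902% (SD, n = 8 each) at bin 20. Blzf1 had 2.60 ± 0.320% against 3.82 ± 0.479% (SD, n = 8 each) at bin 11. Tpm1, a tropomyosin, had 0.29 (SE 0.05) at bin 16 and Slc1a3, the glial glutamate transporter, -0.50 (SE 0.10) at bin 12. The others called were Spock3, Ipo9, 9330182L06Rik, Las1l, Ppp1r12b, Phf10, Rnpep, Herc1, Dos, Anp32e and a group of overlapping genes that holds Dpm1 and Adnp. Pafah1b1, the 20th gene, did not pass as a gene (Simes adjusted p = 0.0624 in edgeR), although its bin 17 did as a bin (adjusted p = 0.0362). The gene-level F test called 227 genes and limma diffSplice 53. The Simes count ranged from 7, without mouse Sample_4738 or Sample_4806, to 42, without mouse Sample_4712.

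The genotype effect did not differ detectably between the sexes. The interaction called 0 genes in edgeR, with 698 at an unadjusted p under 0.05, and 0 in DESeq2 and limma-voom with 744 and 722. Pld4, a microglial exonuclease, had the smallest p, with an interaction of -0.48 (SE 0.10; adjusted p = 0.967 in edgeR). Its levels were 9.999 ± 0.808 CPM in congenic and 8.37 ± 0.204 CPM in wild-type females, and 9.28 ± 0.536 and 10.8 ± 0.615 CPM in males (SD, n = 4 each). Lpcat2, an enzyme of lipid mediator synthesis, had -0.37 (SE 0.08), Tgfbi -0.51 (SE 0.14), Erg, an endothelial transcription factor, -0.47 (SE 0.12), N4bp2 0.57 (SE 0.15), Atad2 0.48 (SE 0.13), Fut11 0.28 (SE 0.07), Ush1g 1.49 (SE 0.38), Sema3b -0.77 (SE 0.21) and 2610028E06Rik -2.41 (SE 0.64). The 95% interval lay within 0.5 of 0 for 66.5% of genes.

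Within females, edgeR called 0 genes by genotype with 366 at an unadjusted p under 0.05, and DESeq2 and limma-voom 0 with 388 and 474. The smallest p values belonged to Sh3bgr with -0.78 (SE 0.19), Lpcat2 with 0.25 (SE 0.06), Edaradd with -1.44 (SE 0.38) and Apod, an apolipoprotein, with 0.33 (SE 0.09), each with an adjusted p of 0.9997 in edgeR, followed by Pld4, Atad2, Ush1g, A630095N17Rik, Emr1 and Spef2. Without the congenic mouse Sample_4804, 17 genes were called, all lower in congenic females. Within males, edgeR called 0 with 491 at that level, and DESeq2 and limma-voom 0 with 528 and 516. Lama4 had -0.36 (SE 0.09), Tgfbi, an extracellular matrix protein, -0.38 (SE 0.10), Upp2 0.41 (SE 0.11), Slc15a2, a peptide transporter, 0.36 (SE 0.10) and Hcn3 -0.33 (SE 0.10), each with an adjusted p of 0.937 in edgeR, among 10 genes with 4930594C11Rik, Tmem161b, Gm7102, 4932438H23Rik and D930028M14Rik.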

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

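The tests in this part were chosen after the results were seen, apart from the tests of neighbouring mouse numbers and of the library of mouse Sample_4806, which were set before their own values were seen. Of 342 groups of 4 or 8 mice examined, 33 held a mouse far from the others by Dixon's ratio, and chance gives about 1 in 20 groups, here 17.1.

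Mouse Sample_4806, a wild-type mouse recorded as female, stood apart in transcripts of the sex chromosomes. It had 2.64 CPM of Xist (other females 951 to 1549), 40.4 of Kdm6a (49.7 to 58.0), 119 of Eif2s3x (175 to 194) and 13.2 of 5530601H04Rik (15.5 to 16.9), and a sex chromosome score of -2.76 (-1.40 to -0.18). A male recorded as female is argued against, since the mouse held 7 counts of 4 Y genes and the males at least 13555. Of all 16 mice it had the highest share of counts in the 10 highest genes (4.02%, others 3.24 to 3.83%) and in Rn45s (0.439%, others 0.160 to 0.376%), but a poor library is argued against as the cause, since 0 of 4420 other genes at 50 CPM or more lay under 10% of the lowest other female, and 0.289% of 8995 genes outside X and Y lay as far below it as the median of 4 genes that escape silencing. A single X chromosome with no Y remains a candidate explanation, since 4 of 4 genes that escape silencing were below every other female, although Ddx3x at 311 CPM lay between the males and the other females, no karyotype was examined, and loss of Xist with both X chromosomes present was not tested.

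The genotype comparison held few small p values, 256 of 16716 genes at an unadjusted p under 0.05 where uniform p values would give 836. Spread in cortical tissue between punches is argued against as the whole cause, since with the cortical score in the model the number fell further, to 144. A chance property of this grouping stays open for genes, since 12 of 100 splits had as few. Splits other than the real one held 169 to 2848 genes with a median of 561. For exon bins it is not firmly excluded. There 1 of 21 splits, the real one, had as few as 2461, the smallest share that 21 splits can give. The others held 2572 to 4961 bins with a median of 3181. Expression that follows mouse number may also contribute and stays open. Genotypes alternated at 15 of 15 neighbouring numbers. Neighbours of 1 sex were more alike than permuted ones (one-sided permutation p = 0.0396, 14 pairs). Their mean correlation, after centring within each sex, was -0.0355. That centring makes correlations between mice negative on average, so the sign does not show that neighbours were unlike. With pairs of neighbouring numbers as a block the number was 424, higher but still under 836. The labels give no litter or date, so what the numbers stand for was not tested.

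Ide, which encodes an insulin-degrading protease, and the first part of the neighbouring Btaf1 parted the mice in the same way, unrelated to the groups of the study. Ide was at 53.5 to 63.8 CPM in mice Sample_4672, Sample_4673, Sample_4677, Sample_4733, Sample_4738, Sample_4739 and Sample_4806, and at 36.5 to 43.0 CPM in the other 9. Of 17 exon bins outside Ide with those 7 mice highest, 14 lay in the neighbouring Btaf1 and Fgfbp3 on chromosome 19, so a duplicated genomic segment present in some of the mice is a candidate explanation, found and tested on the same data. Tissue content or RNA quality that ranked the mice in this way would move other genes too, and is argued against by only 3 such bins outside these genes. Equal chances for every set of 7 mice would give about 15, but mice that share tissue content do not give equal chances. A graded effect could also escape a count of exact matches. A regulatory difference that acts on Ide alone is argued against by 13 of 38 Btaf1 bins following. Cpeb3 and March5, which lie between Btaf1 and Ide, had 0 of 24 and 0 of 11 bins following, which a single unbroken segment would leave unexplained.

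Of the 23 genes called by sex, 12 lie on X or Y, where the real split is bound to differ. For the 11 elsewhere chance is not firmly excluded, as 1 of 100 splits, the real one, called as many and the highest other called 8, and the count was 2 with 1 surrogate variable and 1 without mouse Sample_4672 or Sample_4731. For the 19 genes of exon usage by sex it is not firmly excluded, as 1 of 21 splits called as many, the smallest share that 21 splits can give, with a highest other of 6, while the count was 5 with 1 surrogate variable, 7 without mouse Sample_4738 or Sample_4806 and 2 with Sample_4804 and Sample_4806 both left out. For the 13 lists by sex it is not firmly excluded, as 4 of 100 splits called as many and the highest other called 14, and the count was 9 without mouse Sample_4806 and 1 with an estimated correlation. It could not be excluded for the 1 gene of exon usage by genotype (9 of 21 splits, highest other 4) or the 6 lists by genotype (73 of 100 splits, highest other 16). For the counts of 0 the splits test nothing, since every split calls at least 0: 100 of 100 for genotype with a highest other of 138, 100 of 100 for the interaction (3), 35 of 35 in females (7) and 35 of 35 in males (0). Of the 4 of 100 splits by genotype that called any gene, 1 called 138 and 1 called 110 where the real one called 0, which may point to a structure of the samples, and what those splits separate was not tested.

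Other mice far from the rest of their group were these. In CPM, Tle3 was at 21.3 in wild-type mouse Sample_4732 (others 16.7 to 18.8), C3ar1 at 3.65 in congenic mouse Sample_4673 (2.77 to 3.17), Uty at 21.7 in male Sample_4673 (15.6 to 18.4) and Kdm6a at 41.8 in the same male (32.8 to 36.4). Female Sample_4737 had Kdm5d at 0.701, Ddx3y at 1.01 and Eif2s3y at 0.935, and male Sample_4672 had Xist at 17.6 (1.35 to 3.34). Spry2 was at 62.0 in male Sample_4712 (77.7 to 91.5). Among wild-type males, Pld4 was at 11.7 in Sample_4672, Ush1g at 0.229 in Sample_4712 and 4932438H23Rik at 1.152 in Sample_4732. Among congenic males, Fut11 was at 23.7 in Sample_4671, Slc15a2 at 22.4 in Sample_4733 and Hcn3 at 11.8 in Sample_4731.

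As shares of a gene's exon counts, Lama4 bin 8 was at 2.09% in congenic mouse Sample_4739, Magi2 bin 34 at 0.0682% in wild-type mouse Sample_4672, and in male Sample_4712 Ipo9 bin 36 was at 1.43% and Las1l bin 16 at 2.56%. Among list scores, wild-type mouse Sample_4806 had D1-MSN at -0.37 and dopamine signalling at -0.19, the latter also apart among females. Congenic male Sample_4673 had cytosolic ribosomal proteins at 0.43 (others -0.13 to 0.13) in both groupings, hnRNPs at -0.0649 and interneuron at -0.30. Female Sample_4739 had the interval neighbours at -0.0576, and congenic mouse Sample_4804 had pan-MSN at -0.20.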

How the results depend on the processing

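The alternatives with the cortical score, those of exon usage by sex, upper-quartile scaling for sex, bins counted in every mouse, the list tests without single mice, the block of neighbouring mouse numbers and the fits without 2 or 3 mice together were chosen after the data were seen. The genotype and interaction counts stayed at 0 under every alternative run, and so did the count over Hnrnph1 and Rufy1 bins. The log2 fold changes by genotype changed sign near 0. Hnrnph1, genotype gene expression, was at -0.0118 with 2 surrogate variables, -0.0105 in females alone and -0.0051 with the cortical score, and at -0.0048 to 0.0234 without single mice, below 0 without Sample_4672, Sample_4676, Sample_4712, Sample_4733 or Sample_4739. Rufy1, genotype gene expression, was at 0.0266, 0.0114 and 0.0125 in those settings, 0.0422 in lane 4 alone, and -0.0153 to 0.0144 without single mice, above 0 without Sample_4671, Sample_4673, Sample_4676, Sample_4712 or Sample_4739. Genes called by sex numbered 259 with DESeq2, 12 with 1 surrogate variable, 14 with the cortical score, 59 in wild-type and 9 in congenic mice alone, and 12 to 76 without single mice: 41 without Sample_4671, 12 without Sample_4672, 66 without Sample_4673, 76 without Sample_4712, 12 without Sample_4731, 15 without Sample_4733, 14 without Sample_4734, 40 without Sample_4737, 14 without Sample_4738, 13 without Sample_4753, 13 without Sample_4804 and 15 without Sample_4806. Exon usage by sex gave 227 genes with the F test, 53 with limma diffSplice, 5 with 1 surrogate variable, 9 with the cortical score, and 7 to 42 without single mice: 8 without Sample_4672, 33 without Sample_4676, 42 without Sample_4712, 9 without Sample_4732, 12 without Sample_4734, 29 without Sample_4737, 7 without Sample_4738, 9 without Sample_4804 and 7 without Sample_4806. Exon usage by genotype gave 2 genes with the F test, 0 with limma diffSplice and the cortical score, and 0 to 1 without single mice, with 0 without Sample_4673, Sample_4712, Sample_4734, Sample_4738, Sample_4739 or Sample_4806. The stricter filter, bins counted in every mouse, each lane alone and each sex alone also gave 0, but these removed the only called bin before testing, so they say nothing about it. In females, 0 to 17 genes were called without single mice, with 17 without Sample_4804. Lists by genotype numbered 0 with an estimated correlation, 0 with fry and 3 with the cortical score, and lists by sex 1, 4 and 10, with 5 to 8 by genotype and 9 to 13 by sex without single mice. With Sample_4804 and Sample_4806 both left out, sex gave 13 genes, 2 genes of exon usage and 8 lists, and with Sample_4753 also left out 7 lists, the direction turning for ependyma (p = 0.697). With the cortical score, the direction turned for microglia (p = 0.388) and cortical excitatory neurons (p = 0.973) by genotype and for cortical excitatory neurons by sex (p = 0.424), which that covariate's own construction brings about for the cortical list. For the others the cause was not tested. Among values of single genes, bins and lists, 3333 kept direction and side of the threshold, 346 were weaker, 37 stronger and 21 turned. The labels name no pairs. With pairs of neighbouring numbers of 1 sex as a block in place of sex, 0 genes were called by genotype, 1 gene of exon usage, and 8 lists, 5 of them among the 6, with microglia lost (p = 0.0236) and oligodendrocyte, ependyma and heat shock gained.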

Other observations

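Choroid plexus and ependyma transcripts, from tissue lining the ventricle beside the striatum, varied widely between mice. The choroid plexus score spanned -0.62 to 0.37 and the ependyma score -0.89 to 0.86 on the log2 scale. Ttr, the main secreted protein of the choroid plexus, had a log2 fold change of 1.11 (SE 0.66) by sex and 0.42 (SE 0.65) by genotype, and did not pass in edgeR. The septum and pallidum score spanned -0.57 to 0.64, and the oligodendrocyte score -0.28 to 0.35. Scores of the hnRNPs, at -0.06 to 0.06, and of other splicing factors, at -0.05 to 0.05, varied less.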
